A study of Homo sapiens with 8 samples.

How the data were processed

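Single cells were profiled in fresh tumour biopsies of muscle-invasive bladder cancer, 1 biopsy from each of 8 patients. Per the labels' protocols, the tissue was digested with enzymes, filtered, cleared of red blood cells and checked for viability, and the cells were loaded on a 10x Genomics 5' v2 droplet instrument and sequenced on an Illumina NovaSeq. In this assay a barcode marks the droplet and a unique molecular identifier (UMI) marks each captured RNA molecule. The labels put all 8 biopsies into 1 group, so no group of patients was compared with another. The comparisons are between classes of cells from the same biopsies, and the patient enters each model as a block. Biopsies are named 1 to 8 in the order of deposit, which carries no other meaning.

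The deposited files hold raw counts, the number of UMIs per gene and barcode, for 38606 genes and 35853 barcodes. Per the submitters' processing notes, Cell Ranger 7.1.0 and Seurat were used with the build hg38/GRCh38, while per the file headers the matrices were written by Cell Ranger 9.0.0. The sources used here do not settle which of these versions made the counts. The gene annotation and the treatment of reads that match several near-identical genes are not given in the sources used here, so the values of HLA genes, KLRC1 and CCL3, which have close copies, are less certain than others. Every barcode in the deposited counts had at least 500 UMIs, and no filter on mitochondrial RNA was visible in them, with 53.1% of the barcodes of biopsy 3 above 20% mitochondrial UMIs. Samples were first compared pairwise for duplicate deposits. Over the 28 pairs the lowest chi-square per degree of freedom of the summed counts was 55.2, and at most 48 barcodes were shared, so each biopsy was counted as its own sample.

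Barcodes were kept as cells with at least 500 UMIs, at least 200 detected genes and at most 20% mitochondrial UMIs, which left 26232. Scrublet scores in scanpy 1.11.5 were computed per biopsy. The automatic threshold marked only 30 cells (0.114%), too few for the loading, so the cells with the highest scores were removed instead, at 0.8% per 1000 barcodes. This rule was set after the automatic result was seen, removed 1336 cells and left 24896. Cells were clustered on 2000 variable genes, 30 principal components and 20 neighbours with Leiden at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), leaving out every gene of the tested lists except the 2 background lists. Genes expressed together with list members remained, so the clustering and the list results are not independent. The 37 clusters were named "X-like" from fixed markers, reading the top 10 genes by fold and the markers detected in at least 25% of the cells. A cluster stayed unnamed with under 3 detected markers, with leading genes of another class, or with low depth and no marker among its top genes. A further rule, set after the clusters had been viewed, left a cluster unnamed when it carried at least 4 raised markers of another compartment or 2 among its top 10 genes. In all 9 clusters stayed unnamed, 8 of them by that further rule, and a version without the rule is among the alternatives. The T/NK-like cells were clustered again, and 10 of 15 sub-clusters were named. A first version of that sub-clustering left 1 biopsy with at least 20 Treg-like and 20 CD8 T-like cells. The adopted version, which removes each biopsy's mean, left 4 and was chosen before any differential test. Shares of cells have exact Clopper-Pearson intervals at 95% and, at 0 cells, an upper limit of 3 cells of the total, both for counting error only.

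UMI counts were summed per biopsy and class. Sums of at least 20 cells entered the model, and 7 classes chosen in advance each gave sums from at least 3 biopsies, making 33 sums from 7 biopsies with 32708 to 46238497 UMIs each. Mural-like and mast-like cells, with at least 20 cells in 4 and 3 biopsies, were not among these classes, so every "other class" below is 1 of the 7. Each class was compared with the unweighted mean of the other classes by edgeR 4.0.16 (estimateDisp, robust glmQLFit, glmQLFTest) under R 4.3.3 with TMM scaling, filterByExpr and a patient term. A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05 with an absolute log2 fold change of at least 1. All adjusted p values of single genes below come from this test unless another tool is named. Standard errors (SE) were derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F. A gene with 0 UMIs in every sum of a class has no finite estimate of that class's mean, so its fitted fold depends on the prior count of the tool, and where such a class pulls against the direction of the difference the test returns a p near 1. This left 90 to 333 of the 12334 tested genes per comparison that could not be called. For named genes with another class at 0 UMIs, mean CPM values are given below in place of the fitted fold. Genes used for clustering and the cell type markers were left out of the tested genes. The B-like and plasma-like comparisons are described apart from the others because they were added after the data were seen.

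Within the epithelial-like cells, each cell with at least 2000 UMIs was thinned to 2000 and scored, within its biopsy, by luminal minus basal genes. The cells above the upper and below the lower tertile of each biopsy with at least 60 such cells were summed from all their counts, giving 10 sums. The score genes were left out of the tested genes. In the T/NK-like cells, Treg-like and CD8 T-like sums gave 8 sums. Both comparisons used the same test with the patient as a block, and the pairing comes from cells of the same biopsy.

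The 18 tested gene lists were fixed before the data were examined, as were the markers, comparisons, tests and the rule for naming genes. They cover surface drug targets, immune checkpoints, chemokines and their receptors, extracellular matrix, angiogenesis, MHC class I, MHC class II, interferon response, proliferation, hypoxia and glycolysis, mesenchymal transition, growth factors and cytokines, DNA repair and chromatin targets, neuroendocrine genes, cytotoxic effectors, dissociation stress, and 2 background lists of markers of other cells. Each list was tested with camera from limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, each adjusted by Benjamini-Hochberg over the lists of a comparison. Named genes are up to 4 called members of each list with the largest absolute log2 fold change, 8 fixed targets in the epithelial comparisons, 5 fixed receptors in the T cell comparisons, and, of genes in no list, the 5 highest and 5 lowest with an average log2 CPM of at least 5 and the same sign in every biopsy. Results for 2 genes that this rule names are left out of the text. Genes linked to sex, immune receptor segments, mitochondrial and ribosomal genes were left out by name. CPM values were computed with the TMM-scaled size of each sum. Correlations across biopsies used log2(CPM + 1) means and exact two-sided permutation tests.

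Alternatives planned in advance were RLE and library-size scaling, DESeq2 1.42.0, no filter on low counts, no patient block, at least 50 cells per sum, at most 10% mitochondrial UMIs, doublets kept, Leiden resolution 2, a split at the median of the score, sums of thinned counts, thinning to 1000 UMIs, and each biopsy left out in turn. Added after the data were seen were the naming rule above, at least 1000 UMIs per cell, and a reference in which the sums of all other classes form 1 group, so that differences between those classes count as error. The edgeR fit alone was tested on simulated counts in which only 200 genes were changed, by known amounts. At log2 fold changes of 1.5 and 3 it recovered 65% and 96% for epithelial-like cells (12334 genes). It recovered 87% and 99% for the luminal end (14115) and 90% and 99% for Treg-like cells (6843). False calls were 3 of 164, 10 of 196 and 14 of 203 calls. These rates need not hold for the real contrasts. Gene positions come from GENCODE v29 on GRCh38. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9 were used.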

Results

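The deposited data are single-cell RNA profiles of tumour biopsies from 8 patients with muscle-invasive bladder cancer, a cancer of the bladder lining that has grown into the muscle wall. The labels state the cellular makeup of these tumours as the subject and place all biopsies in 1 group of 8. The files hold 35853 barcodes, from 453 in biopsy 5 to 12554 in biopsy 3, with 1203078 to 78360136 unique molecular identifiers (UMIs) per biopsy. Of these, 24896 cells were used. The median depth of the kept cells was 936.5 UMIs in biopsy 1, 12047 in biopsy 2, 6377 in biopsy 3, 3808 in biopsy 4, 1245 in biopsy 5, 6275 in biopsy 6, 1521 in biopsy 7 and 3413 in biopsy 8. Biopsies 1, 5 and 7 are therefore the shallowest, and values resting on them are the least precise.

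To describe the cellular makeup of each tumour, cells were assigned to classes by their markers and the share of each class was taken within each biopsy. The makeup differed widely between biopsies. Epithelial-like cells, the class that holds tumour cells and any normal bladder lining, made up 91.6% of biopsy 3 (exact 95% interval 90.8 to 92.3%) and 87.7% of biopsy 2 but 0.504% of biopsy 7, with a median of 18.6% over the 8 biopsies. T/NK-like cells, the T and natural killer lymphocytes, made up 62.1% of biopsy 4 (61.0 to 63.3%) against a median of 3.51%. B-like cells reached 62.2% of biopsy 7 (60.5 to 64%) and 40.8% of biopsy 8 (38.4 to 43.1%), while the median was 0.419% and none were named in biopsies 1 and 5.

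Myeloid-like cells, which include macrophages and dendritic cells, ranged from 0.734% to 22.4%, and fibroblast-like cells, which make the connective tissue, from 0.0581% to 13.3%. Endothelial-like cells, which line the vessels, ranged from 0.0692% to 6.82%, mural-like cells, which wrap the vessels, from 0 to 7.83%, and antibody-secreting plasma-like cells from 0.0386% to 13.2%. Mast-like cells had a median of 0.258% and plasmacytoid dendritic-like cells one of 0.0863%. No cell was named neutrophil-like or erythroid-like, which by counting error alone allows a share of up to 0.0461% in biopsy 4, the largest, and up to 0.706% in biopsy 5, the smallest. In biopsies 1 and 5, 88.3% (87.1 to 89.5%) and 88.9% (85.6 to 91.8%) of the cells stayed unnamed, since their clusters carried markers of several compartments, against 0.113% to 6.57% in the other 6 biopsies. Shares in these 2 biopsies depend on the naming rule. With clusters of mixed markers named, biopsy 1 was 85.7% fibroblast-like and biopsy 5 was 92% myeloid-like, and at Leiden resolution 2 biopsy 5 was 64% myeloid-like. At that resolution biopsy 2 was 54.6% epithelial-like, with 39.7% unnamed. The shares are of cells that survived dissociation, loading and the filters, and the intervals cover counting error only.

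**Figure D1:**
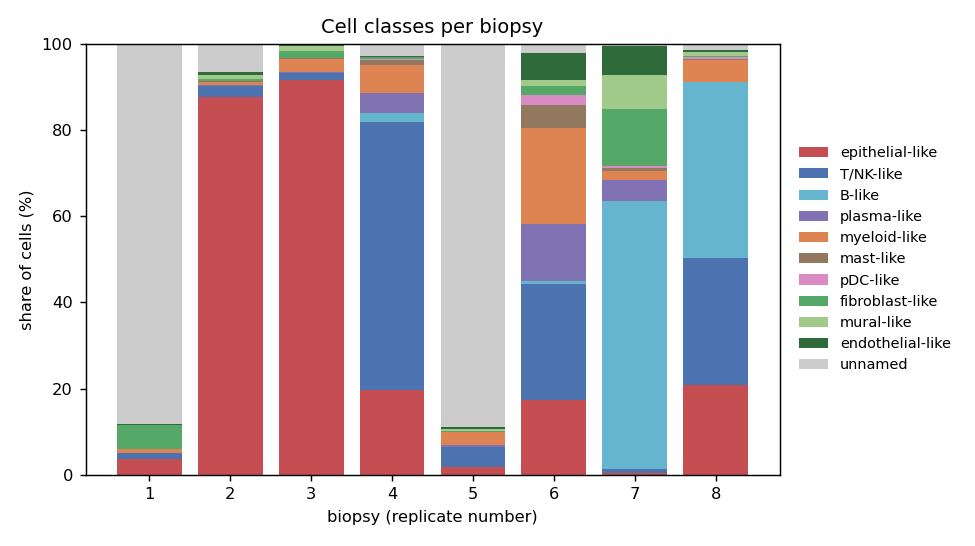
Stacked bars of the share of cells (%) in each class for biopsies 1 to 8. Epithelial-like cells fill 87.7% and 91.6% of biopsies 2 and 3, T/NK-like cells 62.1% of biopsy 4 and B-like cells 62.2% of biopsy 7, and unnamed cells 88.3% and 88.9% of biopsies 1 and 5.

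T/NK-like cells were divided further. CD8 T-like cells, the class of killer T cells, made up 34.1% of the T/NK-like cells in biopsy 3, 74.1% in biopsy 4 (72.7 to 75.4%), 20.9% in biopsy 6 and 38.9% in biopsy 8. Treg-like cells, the T cells that restrain immune responses, made up 25%, 11.4%, 23.3% and 7.66% of the same populations. CD4 T-like cells reached 36.3% in biopsy 8. Unnamed sub-clusters held 19.3%, 6.01%, 46.5% and 4.13% of the T/NK-like cells of biopsies 3, 4, 6 and 8, so the shares in biopsy 6 may be too low.

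To find which therapeutic targets the epithelial compartment expresses, epithelial-like sums of 6 biopsies (105 to 4848 cells each) were compared with the mean of the other classes. Malignant and normal epithelium were not told apart, and 9 of the 11 epithelial-like clusters had over 80% of their cells from 1 biopsy. Epithelial-like cells expressed RNA of several surface proteins against which antibody drugs are directed. NECTIN4, which encodes the adhesion protein nectin-4, averaged 111 ± 63.6 CPM (SD, n = 6), and the receptor tyrosine kinases ERBB2, FGFR3 and EGFR 140 ± 95.7, 88.7 ± 108 and 283 ± 317 CPM. Each of these 4 genes was higher in 6 of 6 biopsies. Such counts of biopsies, here and below, set a sum against the mean log2 CPM of the other classes with a sum in that biopsy. Biopsy 2 gave only a T/NK-like sum besides, and biopsy 8 no fibroblast-like or endothelial-like sum. They are therefore not counts of biopsies in which a gene exceeds every other class. CD274, which encodes the checkpoint ligand PD-L1, and FAP, a protease of activated fibroblasts, were not called. The T/NK-like sums of the same biopsies, given for reference, held means of 1.49 CPM of NECTIN4, 7.03 of ERBB2, 5.76 of FGFR3 and 11.4 of EGFR.

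The log2 fold change was 5.91 ± 0.38 for NECTIN4 (SE, adjusted p = 3.1e-10), 4.28 ± 0.35 for ERBB2 (9.8e-10), 3.94 ± 0.36 for FGFR3 (3.9e-09) and 4.06 ± 0.49 for EGFR (3.1e-07). Fibroblast-like sums also held EGFR, at a mean of 187 CPM. CD274 differed by 0.47 ± 0.47 (adjusted p = 0.47, higher in 3 of 6), and by -0.52 with the other classes as 1 group. FAP differed by 0.21 ± 0.52 (adjusted p = 0.81, higher in 4 of 6), a value that turned to -0.07 without biopsy 1 and -1.52 without biopsy 4, and it was called higher with at most 10% mitochondrial UMIs (1.39, adjusted p = 0.0441). CD276, which encodes the ligand B7-H3, averaged 35.9 ± 12.9 CPM and was called higher (adjusted p = 1.4e-05, 6 of 6), although fibroblast-like sums held 75.2 CPM and endothelial-like sums 54.6. CD276 was not called with the other classes as 1 group (0.87, adjusted p = 0.642). The same biopsies differed among themselves, FGFR3 from 11.5 to 297 CPM and EGFR from 45.9 to 854, with 854 in biopsy 4 and 460 in biopsy 1.

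On GRCh38 with GENCODE v29, NECTIN4 (ENSG00000143217) spans chromosome 1, 161070995 to 161089599, on the minus strand. ERBB2 (ENSG00000141736) spans chromosome 17, 39687914 to 39730426, FGFR3 (ENSG00000068078) chromosome 4, 1793293 to 1808872, and EGFR (ENSG00000146648) chromosome 7, 55019021 to 55211628, all on the plus strand. CD274 (ENSG00000120217) spans chromosome 9, 5450503 to 5470566, and CD276 (ENSG00000103855) chromosome 15, 73683966 to 73714518, on the plus strand. FAP (ENSG00000078098) spans chromosome 2, 162170684 to 162245151, on the minus strand. Counts are over whole genes, so no exon or isoform can be told from them.

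**Figure D2:**
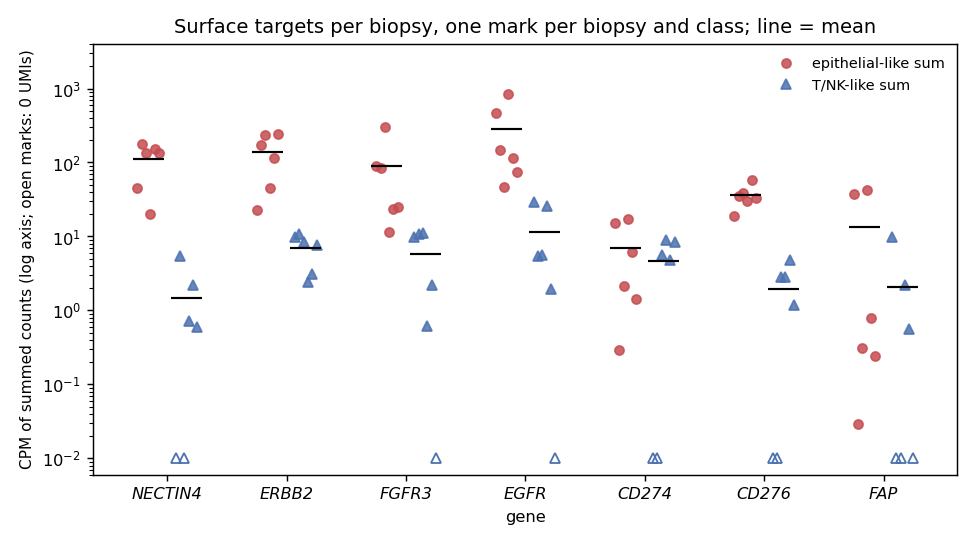
CPM of 7 surface targets on a log axis, 1 mark per biopsy for the epithelial-like sums (circles, 6 biopsies) and the T/NK-like sums (triangles), with a line at the mean of each and open marks at 0 UMIs. NECTIN4 runs from 20.1 to 179 CPM in the epithelial-like sums against a mean of 1.49 in the T/NK-like sums, while FAP lies at 37.7 and 41.8 CPM in biopsies 1 and 4 and below 1 in the other 4.

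Over the fixed list of surface drug targets, 20 of 35 tested members were higher in epithelial-like cells and 6 lower, the same numbers when adjusted over the list alone (camera adjusted p = 2.2e-06, and adjusted p = 0.028 with an estimated correlation). Among them the growth factor receptor ERBB3 rose by 5.25 ± 0.40 on the log2 scale (adjusted p = 3.2e-10), the adhesion protein SLITRK6 averaged 63.0 ± 103 CPM against at most 5.54 in any other class, and the mucin MUC1 62.2 ± 53.4 CPM against at most 5.02. Without biopsy 6 the number of lower members was 3.

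Antigen presentation by MHC class II ran the other way. Of 15 tested members 13 were lower and 0 higher (13 and 0 adjusted over the list alone, with 1 higher at an unadjusted p under 0.05 and 0 higher by DESeq2), at a median log2 fold change of -3.14 (camera adjusted p = 1.6e-11, and adjusted p = 0.0356 with an estimated correlation). HLA-DQA1, HLA-DPA1, HLA-DPB1 and HLA-DQB1, which encode chains of the class II molecules, differed by -4.66 ± 0.74, -4.39 ± 0.62, -4.19 ± 0.62 and -3.68 ± 0.55, each lower in 6 of 6 biopsies. Without biopsy 1 or without biopsy 4, 1 member was called higher. Of the 20 MHC class I members, 9 were lower and 0 higher (9 and 0 adjusted over the list alone, with 3 higher at an unadjusted p under 0.05 and 0 higher by DESeq2), led by NLRC5, a transcription activator of class I genes, at -2.15 ± 0.34, HLA-F at -1.99 ± 0.55 and HLA-E at -1.93 ± 0.28, with the immunoproteasome subunit gene PSMB9 also lower (adjusted p = 0.0001). The camera adjusted p for class I was 9.9e-07, and the adjusted p was 0.164 with an estimated correlation.

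Immune checkpoint genes were mostly lower, 19 of 37 against 4 higher (21 and 4 adjusted over the list alone, camera adjusted p = 2.2e-06, and adjusted p = 0.0379 with an estimated correlation). ENTPD1, which encodes the ectonucleotidase CD39, differed by -4.80 ± 0.53 (adjusted p = 8.0e-08) and CD200 by -4.18 ± 0.79 (0.00019). The adenosine receptor gene ADORA2A differed by -4.36 ± 0.65 and lost its call without biopsy 1 (adjusted p = 1). SIGLEC15, an inhibitory lectin gene, was higher at 11.1 ± 9.04 CPM against at most 2.54 in another class (adjusted p = 3.3e-06, 5 of 6 biopsies). Without biopsy 6, 9 members were lower.

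Cell cycle genes were higher in epithelial-like cells, 33 of 43 with 0 lower (37 and 0 adjusted over the list alone, with 0 lower at an unadjusted p under 0.05 and 20 higher and 0 lower by DESeq2). The camera adjusted p was 0.00037, and 0.504 with an estimated correlation. The replication genes MCM4, CDT1, CDC45 and GINS2 rose by 2.53 ± 0.36, 3.18 ± 0.73, 3.04 ± 0.64 and 2.52 ± 0.55. T/NK-like sums held 19.1 CPM of CDC45, against 17.8. The count fell to 14 without biopsy 4 and 12 without biopsy 6. Of these 4 genes only MCM4 was called with the other classes as 1 group. Hypoxia and glycolysis genes were higher in 18 of 35 and lower in 1 (18 and 1 adjusted over the list alone, camera adjusted p = 0.0014, and adjusted p = 0.308 with an estimated correlation). CA9, a carbonic anhydrase induced by low oxygen, averaged 73.3 ± 118 CPM against at most 7.55 in another class. CA12 averaged 68.7 ± 81.8 CPM against 50.2 in fibroblast-like sums, and ANGPTL4, up by 4.74 ± 0.63, 67.9 against 82.2. Their calls ended with the other classes as 1 group (adjusted p = 0.0512 and 0.0605). The glucose transporter SLC2A3 differed by -4.40 ± 0.54, and without biopsy 3 or 4, 2 members were lower.

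Of 45 growth factor and cytokine genes, 16 were higher and 5 lower (16 and 5 adjusted over the list alone, 10 and 8 by DESeq2, camera adjusted p = 0.3, 10 higher without biopsy 4, and 3 lower without biopsy 6 or 7). WNT7B averaged 36.5 ± 14.4 CPM (adjusted p = 1.1e-07, 6 of 6 biopsies) and the EGF-family ligand BTC 14.9 ± 12.4 CPM (2.2e-06, 5 of 6). EREG, another EGF-family ligand, averaged 35.7 ± 55.6 CPM and was called higher (0.0031), although fibroblast-like sums held 136 CPM, from 667 in biopsy 6 and at most 12.7 in the other 4, and its call ended with the other classes as 1 group (adjusted p = 0.232). SHH averaged 12.9 ± 14.6 CPM (0.00021, 4 of 6) and lost its call without biopsy 6 or biopsy 8. DNA repair and chromatin genes were higher in 14 of 48 and lower in 2 (14 and 2 adjusted over the list alone, camera adjusted p = 0.837), with a median of 0.16 and a mean of 0.45 while camera pointed down. Cyclin E1, CCNE1, averaged 15.8 ± 12.3 CPM against at most 5.58 in another class and TUBB3 rose by 3.45 ± 0.59, while SLFN11, whose product sensitises cells to DNA damage, differed by -2.82 ± 0.38. Without biopsy 6, 7 members of the list were higher. Of the 4 neuroendocrine genes tested, UCHL1 was higher (2.01 ± 0.63, adjusted p = 0.0131, 5 of 6, 9.31 CPM against 20.3 in fibroblast-like sums). Its call was lost without biopsy 6 (2.38, adjusted p = 0.131) and with the other classes as 1 group (0.93). Adjusted over the list alone 2 were higher and 1 lower. Called higher were 4 without biopsy 1, 3 or 7, 2 without biopsy 8 and 0 without biopsy 6, and 1 was lower without biopsy 1, 4 or 7.

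In all, 2398 of 12334 tested genes were higher and 880 lower in epithelial-like cells. Outside the lists, the highest were RAB25, a vesicle transport gene of epithelia (5.32 ± 0.36), RNF128 (5.20 ± 0.59), BTBD16 (5.18 ± 0.42), GRHL2, an epithelial transcription factor (4.72 ± 0.36), and ITGB8 (43.7 ± 44.0 CPM, against 133 in fibroblast-like sums). The lowest were GYPC (-6.65 ± 0.55), ABI3 (-5.57 ± 0.64), GPR65 (-5.39 ± 0.70), ST8SIA4 (-5.20 ± 0.53) and RCSD1 (-4.99 ± 0.62). With the other classes as 1 group, 1176 were higher and 610 lower, and without biopsy 6, 578 were lower.

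To describe the connective tissue of the tumours, fibroblast-like sums of 5 biopsies (28 to 397 cells) were compared with the other classes. Fibroblast-like cells carried nearly the whole extracellular matrix list, 46 of 47 tested members higher and 0 lower (46 and 0 adjusted over the list alone, with 0 lower at an unadjusted p under 0.05 and by DESeq2). The median log2 fold change was 6.06 (camera adjusted p = 4.8e-62, and adjusted p = 3.9e-06 with an estimated correlation). COL8A1, a collagen gene, rose by 9.31 ± 0.77 (adjusted p = 4.8e-10). THBS2 averaged 477 ± 274 CPM against at most 57.9 in another class, POSTN, which encodes periostin, 605 ± 289 against 40.4, and the matrix protease gene MMP3 418 ± 713 against 0.247. MMP3 was higher in 4 of 5 biopsies and lost its call without biopsy 4 (adjusted p = 1).

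Of 35 surface drug targets, 19 were higher in fibroblast-like cells and 0 lower (19 and 0 adjusted over the list alone, with 0 lower at an unadjusted p under 0.05 and 17 higher and 1 lower by DESeq2). The camera adjusted p was 1.8e-06, and 0.0023 with an estimated correlation. PDGFRB, a receptor of stromal cells, rose by 6.86 ± 0.56 (adjusted p = 3.9e-10) and F3, tissue factor, by 6.16 ± 0.70. ROR2 averaged 148 ± 109 CPM against at most 13.8 in another class. LRRC15 averaged 14.9 ± 14.0 CPM, was higher in 3 of 5 biopsies and lost its call without biopsy 3 or biopsy 4 (adjusted p = 1 for each). Without biopsy 1, 2 members were lower.

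Growth factor and cytokine genes were higher in 27 of 45 and lower in 0 (28 and 0 adjusted over the list alone, with 0 lower at an unadjusted p under 0.05 and 26 higher and 1 lower by DESeq2). The camera adjusted p was 7.5e-08, and 0.0054 with an estimated correlation. BMP4 averaged 186 ± 136 CPM (adjusted p = 1.6e-12), WNT2 125 ± 117 and the interleukin 6-family cytokine IL11 144 ± 272, each higher in 5 of 5, and IL24 125 ± 235, higher in 3 of 5. Without biopsy 6, 1 member was lower. Of 42 chemokine and receptor genes, 16 were higher and 6 lower (17 and 6 adjusted over the list alone, camera adjusted p = 0.467). CXCL14 rose by 8.56 ± 0.99 (adjusted p = 3.9e-07), the eosinophil attractant CCL11 averaged 333 ± 413 CPM against at most 2.12 in another class, and CXCL5 87.0 ± 168 CPM in 3 of 5 biopsies, a call that ended with the other classes as 1 group (adjusted p = 0.432). CXCR5, the B cell homing receptor, had 0 UMIs in all 5 sums. A floor of 3 UMIs over the class lay about 24.0-fold below the arithmetic mean CPM of the other classes. B-like sums carried that mean (97.0 CPM, at most 4.42 in another class). The call of CXCR5 was lost without biopsy 6 or 7 (adjusted p = 1 and 0.0954) and with the other classes as 1 group (0.217). Without biopsy 7, 9 chemokine members were higher, and 3, 1 and 1 were lower without biopsies 3, 6 and 7.

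The 18 epithelial background markers, most of them outside the tested genes, gave 1 lower member, SPINT2 (-1.49 ± 0.43), which lost its call without biopsy 6 (-1.09, adjusted p = 0.175) and with the other classes as 1 group (adjusted p = 0.177). Adjusted over the list alone, 6 were lower and 1 higher. The fibroblast-like sum of biopsy 1 held 0.479% of its UMIs in this list, with KRT5 in 78% of cells, and KRT5 was in 42.9% of the fibroblast-like cells of biopsy 4, so RNA of epithelial cells is present in these sums. In all, 1925 genes were higher and 597 lower, and 630 and 136 with the other classes as 1 group. Outside the lists, MXRA8 (8.22 ± 0.42), SVEP1 (8.11 ± 0.44), FKBP10, a collagen-folding chaperone gene (7.76 ± 0.54), and CACNA2D1 (6.56 ± 0.60) were among the highest, with ISLR at 218 ± 110 CPM against at most 1.46. ITGB7 (-5.37 ± 0.65), TPD52 (-4.42 ± 0.61), IRAG2 (-4.34 ± 0.80), LY75 (-4.02 ± 0.59) and NCF4 (-3.99 ± 0.92, lost without biopsy 7 at an adjusted p of 1) were the lowest.

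To describe the vessels, endothelial-like sums of 3 biopsies (21 to 203 cells) were compared with the other classes. The angiogenesis list was higher in 29 of 39 members and lower in 2 (30 and 3 adjusted over the list alone), at a median of 5.24 (camera adjusted p = 1.2e-48, and adjusted p = 3.0e-06 with an estimated correlation). KDR and FLT1, the receptors of vascular endothelial growth factor, rose by 9.27 ± 0.30 (adjusted p = 1.6e-14) and 7.82 ± 0.46 (2.0e-12) in 3 of 3 biopsies. ESM1 averaged 384 ± 571 CPM, the apelin receptor APLNR 84.2 ± 41.9, the transcription factor SOX17 100 ± 26.6 and ROBO4 174 ± 21.8, each under 1 CPM in the other 6 classes compared, which leave out mural-like and mast-like cells. Without biopsy 6 or 7, 1 member was lower.

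Of 47 matrix genes 25 were higher and 0 lower (27 and 0 adjusted over the list alone, with 0 lower at an unadjusted p under 0.05 and by DESeq2, camera adjusted p = 1.0e-14, and adjusted p = 0.00067 with an estimated correlation). HSPG2, the basement membrane proteoglycan perlecan, rose by 7.36 ± 0.33, and the basement membrane collagens COL4A1 and COL4A2 by 7.34 ± 0.44 and 6.72 ± 0.52. SULF1 averaged 77.7 ± 65.0 CPM against 434 in fibroblast-like sums. The calls of COL4A1, COL4A2 and SULF1 ended with the other classes as 1 group (adjusted p = 0.305, 0.324 and 0.701). Of 35 surface drug targets 11 were higher and 3 lower (11 and 5 adjusted over the list alone), with a median of -0.55 and a mean of 0.37 while camera pointed up (adjusted p = 0.0043, and adjusted p = 0.0621 with an estimated correlation). With the 2 members at 0 UMIs set to their bound, that median was -0.67. FAP rose by 6.02 ± 0.56 (76.6 CPM, against 125 in fibroblast-like sums), a call that ended with the other classes as 1 group (2.59, adjusted p = 0.465). CD38 differed by -5.85 ± 1.56 and was not called without biopsy 6 (-9.97, adjusted p = 0.148) or biopsy 7 (-5.16, adjusted p = 0.0636), where 1 member of the list was lower in each case.

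Of 15 MHC class II members 2 were lower and 0 higher in endothelial-like cells (2 and 0 adjusted over the list alone, with 0 higher at an unadjusted p under 0.05 and by DESeq2, camera adjusted p = 0.0332, and adjusted p = 0.374 with an estimated correlation). They were IFI30, a lysosomal reductase gene (-3.05 ± 0.64), and the protease gene CTSS (-2.19 ± 0.55), which was not called without biopsy 6 (-2.50, adjusted p = 0.0569), where 1 member was lower. SPINT2 differed by -3.82 ± 0.64, and 13 of the 18 epithelial background markers were lower and 0 higher adjusted over the list alone. In all, 1435 genes were higher and 553 lower, 2169 and 344 with library-size scaling, and 239 and 47 with the other classes as 1 group. Without biopsy 6 the total of 1988 was 1060. Outside the lists, ZNF521 (6.17 ± 0.40), GASK1B (5.87 ± 0.45), CAVIN1, a component of caveolae (5.68 ± 0.47), EHD2 (5.66 ± 0.58) and BCAM (5.61 ± 0.38) were the highest. BHLHE41, CHPF and ITGB8 had 0 UMIs in all 3 sums. A floor of 3 UMIs over the class lay about 35.9-fold, 47.0-fold and 25.4-fold below the arithmetic mean CPM of the other classes. NOTCH2 (-6.93 ± 1.02) and GLIPR1 (-6.27 ± 1.46) followed. The calls of ITGB8 and GLIPR1 were lost without biopsy 6 (adjusted p = 0.0944 and 0.0758). With the other classes as 1 group ZNF521, GASK1B, CAVIN1, EHD2, BHLHE41, CHPF, ITGB8, SPINT2, IFI30, CTSS and CD38 were not called, while KDR, FLT1, ESM1, APLNR, SOX17, ROBO4, HSPG2, BCAM, NOTCH2 and GLIPR1 were.

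To describe the macrophages and dendritic cells, myeloid-like sums of 6 biopsies (26 to 558 cells) were compared with the other classes. Myeloid-like cells carried the MHC class II machinery, 14 of 15 members higher and 0 lower (14 and 0 adjusted over the list alone, with 0 lower at an unadjusted p under 0.05 and by DESeq2). The median was 4.60 (camera adjusted p = 2.6e-34, and adjusted p = 7.6e-05 with an estimated correlation). IFI30, HLA-DRA, HLA-DQA1 and HLA-DPB1 rose by 5.42 ± 0.31, 5.39 ± 0.47, 5.28 ± 0.50 and 5.07 ± 0.43, each in 6 of 6 biopsies. They also carried many checkpoint genes, 19 of 37 higher and 2 lower (20 and 2 adjusted over the list alone, camera adjusted p = 1.9e-09, and adjusted p = 0.0141 with an estimated correlation). CD86 and CD80, the ligands of CD28 and CTLA-4, rose by 6.25 ± 0.49 and 5.44 ± 0.38, the macrophage receptor VSIG4 averaged 98.4 ± 68.6 CPM against at most 2.55 in another class, and SIGLEC10 50.6 ± 24.7 against 38.9 in B-like sums. Without biopsy 1, 1 checkpoint member was lower, and without biopsy 6, 0 were.

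Of 42 chemokine and receptor genes, 25 were higher and 1 lower (25 and 2 adjusted over the list alone), at a median of 4.08 (camera adjusted p = 4.3e-10, and adjusted p = 0.0041 with an estimated correlation). CXCL9, an interferon-induced attractant of T cells, rose by 6.74 ± 0.45 (adjusted p = 3.8e-11, 6 of 6) and CCL18 by 6.62 ± 0.55 (5 of 6). CCL19 averaged 127 ± 272 CPM in 4 of 6 biopsies, and CXCL5 36.2 ± 45.7 CPM against 87.0 in fibroblast-like sums, a call that ended with the other classes as 1 group (adjusted p = 0.0922). Without biopsy 2, 3, 4, 6, 7 or 8, 0 chemokine members were lower. Growth factor and cytokine genes were higher in 14 of 45 and lower in 5 (15 and 5 adjusted over the list alone, camera adjusted p = 0.00091, and adjusted p = 0.0189 with an estimated correlation). IL1B, a cytokine of inflammation, rose by 7.13 ± 0.59 (adjusted p = 8.1e-10) and IL10, which dampens it, averaged 33.2 ± 27.9 CPM against at most 13.2 (1.5e-06). EREG averaged 45.4 ± 51.1 CPM against 136 in fibroblast-like sums (667 in biopsy 6, at most 12.7 in the other 4), and its call ended with the other classes as 1 group (adjusted p = 0.351). WNT10A differed by -5.08 ± 1.31 and lost its call without biopsy 6 (adjusted p = 1). Without biopsies 4 and 6, 2 and 1 members were lower.

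The epithelial background list gave SPINT2 as higher (1.46 ± 0.31), which was not called with the other classes as 1 group (0.29), and adjusted over the list alone 1 member was higher and 8 lower. In all, 1395 genes were higher and 1302 lower in myeloid-like cells, 1842 and 729 with library-size scaling, and 610 and 598 with the other classes as 1 group. The lower count was 823, 758, 566 and 763 without biopsies 3, 4, 6 and 7, so the near-even balance does not hold. Outside the lists, CALHM6 (4.89 ± 0.49), CD84 (4.68 ± 0.46), FAM20C (4.66 ± 0.64), the inhibitory receptor LILRB1 (4.34 ± 0.32) and MARCHF1, a ligase that acts on MHC class II (4.34 ± 0.31), were the highest, and FAM20C was not called with the other classes as 1 group (adjusted p = 0.236). FKBP10 (-5.19 ± 1.57), F2R (-3.80 ± 0.78), RRAS2 (-3.66 ± 0.36), CADPS2 (-3.50 ± 0.44) and ABLIM1 (-3.44 ± 0.55) were the lowest, with FKBP10 lost without biopsy 6 or 7 (adjusted p = 1 for each) and with the other classes as 1 group (adjusted p = 0.0503).

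To describe the lymphocytes on which checkpoint drugs act, T/NK-like sums of 7 biopsies (27 to 4043 cells) were compared with the other classes. As a class, T/NK-like cells expressed checkpoint receptors and cytotoxic genes, and their co-expression in single cells was not tested. TIGIT, CTLA4, PDCD1, which encodes PD-1, and LAG3 rose by 6.90 ± 0.47, 6.82 ± 0.49, 5.97 ± 0.50 and 5.10 ± 0.35, each in 7 of 7 biopsies (adjusted p = 1.9e-10, 2.4e-10, 1.7e-09 and 1.9e-10). HAVCR2, which encodes TIM-3, rose by 2.96 ± 0.34 (3.6e-07, 7 of 7), although myeloid-like sums held more of it (117 CPM against 91.9 ± 98.4), and it was not called with the other classes as 1 group (1.58, adjusted p = 0.298). The costimulator ICOS rose by 7.34 ± 0.58, and KLRC1, an inhibitory receptor gene of natural killer cells, averaged 94.2 ± 101 CPM against at most 2.19 in another class. On GRCh38, PDCD1 (ENSG00000188389) spans chromosome 2, 241849881 to 241858908, on the minus strand, CTLA4 (ENSG00000163599) chromosome 2, 203867771 to 203873965, and TIGIT (ENSG00000181847) chromosome 3, 114276913 to 114310288, on the plus strand. LAG3 (ENSG00000089692) spans chromosome 12, 6772512 to 6778455, on the plus strand, and HAVCR2 (ENSG00000135077) chromosome 5, 157085832 to 157142869, on the minus strand.

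Of 37 checkpoint genes 20 were higher and 4 lower (20 and 4 adjusted over the list alone, camera adjusted p = 1.0e-16, and adjusted p = 0.0009 with an estimated correlation), with 2 lower without biopsy 4, 6 or 7. Cytotoxic effectors were higher in 23 of 25 and lower in 0 (23 and 0 adjusted over the list alone, with 0 lower at an unadjusted p under 0.05 and by DESeq2, camera adjusted p = 9.8e-37, and adjusted p = 4.6e-05 with an estimated correlation). The pore-forming protein gene PRF1 rose by 8.54 ± 0.61 and the granzyme gene GZMA by 8.04 ± 0.57, each in 7 of 7, while GZMM averaged 159 ± 90.1 CPM against at most 3.13 in another class and FGFBP2 51.3 ± 65.2 against 0.508. Chemokine and receptor genes were higher in 19 of 42 and lower in 5 (19 and 8 adjusted over the list alone), with a median of -0.81 and a mean of 1.07 while camera pointed up (adjusted p = 3.4e-07, and adjusted p = 0.0056 with an estimated correlation). CCL5 rose by 7.20 ± 0.46 and CXCR6, a receptor of tissue-resident T cells, by 6.74 ± 0.50, with CCR4 at 39.3 ± 35.8 CPM and CCR8 at 25.5 ± 24.3 CPM against at most 0.83 and 1.59 in another class. Without biopsies 4, 6 and 7, 1, 1 and 3 members were lower.

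Cell cycle genes were higher in 28 of 43 and lower in 0 (32 and 0 adjusted over the list alone, with 0 lower at an unadjusted p under 0.05 and 20 higher and 0 lower by DESeq2). The camera adjusted p was 2.0e-09, and 0.181 with an estimated correlation. TYMS, CDT1, CDC45 and RRM2 rose by 2.43 ± 0.50, 2.86 ± 0.70, 2.63 ± 0.62 and 2.49 ± 0.66. Of these, CDT1, CDC45 and RRM2 were not called without biopsy 6 (adjusted p = 0.087, 0.0542 and 0.131), none of the 4 was with the other classes as 1 group, and the count of 28 was 12 without biopsy 4 and 6 without biopsy 6. The epithelial background list gave 1 lower member, SPINT2 (-1.37 ± 0.37), which was not called without biopsy 6 (-1.11, adjusted p = 0.12) or with the other classes as 1 group (adjusted p = 0.0552). Adjusted over the list alone, 1 was lower and 0 higher, with 0 higher at an unadjusted p under 0.05. The markers of that list held a median of 0.0998% of the UMIs of T/NK-like sums, against 1.74% in epithelial-like sums.

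In all, 954 genes were higher and 1283 lower in T/NK-like cells, 1883 and 852 with library-size scaling, which shifts the median of all genes, and 316 and 785 with the other classes as 1 group. Without biopsies 4 and 6 the lower count was 854 and 806. Outside the lists the T cell signalling genes SIT1 (5.44 ± 0.49), LAT (5.26 ± 0.39) and SH2D2A (5.25 ± 0.36) were the highest, followed by GIMAP5 (4.84 ± 0.55) and DOK2 (4.72 ± 0.48), which were not called with the other classes as 1 group (adjusted p = 0.0971 and 0.151). LRRK1 (-5.23 ± 0.52), TBC1D9 (-5.05 ± 0.55), PKIG (-4.85 ± 0.41), IL13RA1 (-4.69 ± 0.36) and the B cell adaptor BLNK (-4.43 ± 0.67) were the lowest.

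**Figure D3:**
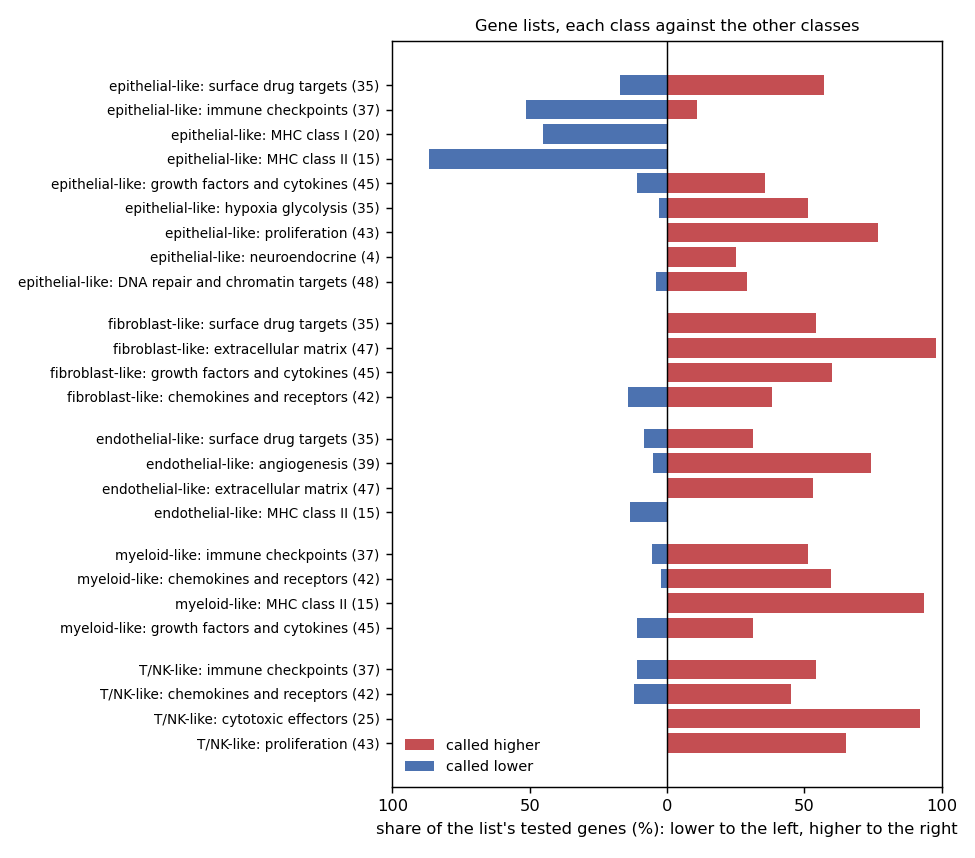
Share of the tested genes of each list (number in brackets) that were called higher (right) or lower (left) in each of 5 classes against the other classes. Extracellular matrix genes are nearly all higher in fibroblast-like cells (46 of 47) and MHC class II genes are higher in myeloid-like (14 of 15) and lower in epithelial-like cells (13 of 15).

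To compare differentiation states within the epithelial compartment, the luminal and basal ends of the epithelial-like cells were set against each other within 5 biopsies. Luminal genes mark the surface layers of the bladder lining and basal genes the layer below. RARRES1 (2.56 ± 0.22), the tight junction gene CLDN3 (2.44 ± 0.24), GDPD3 (2.25 ± 0.27), the sodium channel subunit SCNN1B (1.82 ± 0.19) and CAPN5 (1.36 ± 0.16) were higher at the luminal end in 5 of 5 biopsies. The gap junction gene GJB2 (-2.42 ± 0.30), LY6D (-1.71 ± 0.20), SH3PXD2A (-1.44 ± 0.14) and EPHB6 (-1.30 ± 0.16) were lower in 5 of 5, with adjusted p from 0.0118 to 0.037 over these 9 genes. None of the 9 was called without biopsy 3 (adjusted p from 0.0572 to 0.157) or without biopsy 8 (0.125 to 0.142). Without biopsy 2 RARRES1, GDPD3, SCNN1B, CAPN5, GJB2 and EPHB6 were not called (0.0549 to 0.14), and GJB2 was not called without biopsy 6 (0.057). None of the 9 was called with a split at the median of the score or without the patient block, where edgeR called 0 genes (3230 and 187 at an unadjusted p under 0.05). The ends are parts of a range and not cell types, since 43.1%, 36.2%, 50%, 46.4% and 48.0% of the scored cells of biopsies 2, 3, 4, 6 and 8 lay within 0.1 score units of a boundary.

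In all, 15 of 14115 tested genes were higher and 5 lower, with 3505 at an unadjusted p under 0.05, and library-size scaling gave 20 and 15. DESeq2 called 159 higher and 226 lower. Scores built from 20 random lists of as many genes of like expression gave at least as many calls in 15 lists, with a median of 41.5 and a range of 1 to 384, so the number of calls is not particular to luminal and basal genes. The total of 20 was 5 without biopsy 2, 1 without biopsy 3, 217 without biopsy 4, 33 without biopsy 6 and 0 without biopsy 8, where 2871 genes had an unadjusted p under 0.05. Of the fixed targets, NECTIN4 differed by 0.49 ± 0.17 (adjusted p = 0.14) and ERBB2 by 0.68 ± 0.23 (0.14), each higher at the luminal end in 4 of 5 biopsies, and EGFR by -0.81 ± 0.28 (0.14), lower in 5 of 5. FGFR3 (-0.29 ± 0.24, adjusted p = 0.49), CD274 (-0.81 ± 0.56, 0.4) and CD276 (0.11 ± 0.15, 0.69) were not called either, and FAP was too low to be tested. The value of CD276 turned to -0.02 with library-size scaling, to -0.34 in sums of thinned counts and to -0.01 without biopsy 6.

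No member of any list was called by edgeR over all genes tested, higher or lower, at the luminal end. The mesenchymal transition list came nearest, with 6 of 24 members lower adjusted over the list alone, 10 lower and 0 higher at an unadjusted p under 0.05 and 8 lower by DESeq2, at a median of -1.19 (camera adjusted p = 8.6e-08, and adjusted p = 0.727 with an estimated correlation). Proliferation genes had 0 of 43 called adjusted over the list alone, 17 lower at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 1.2e-06, and adjusted p = 0.727 with an estimated correlation). Interferon response genes had 0 of 42 adjusted over the list alone, 5 higher at an unadjusted p under 0.05 and 0 by DESeq2 (camera up, adjusted p = 0.0289, and adjusted p = 0.841 with an estimated correlation). DNA repair and chromatin targets had 0 of 48 adjusted over the list alone, 10 lower at an unadjusted p under 0.05 and 0 by DESeq2 (camera down, adjusted p = 0.012, and adjusted p = 0.727 with an estimated correlation). Growth factors and cytokines had 1 higher and 1 lower of 29 adjusted over the list alone, 3 higher and 5 lower at an unadjusted p under 0.05 and 1 higher and 3 lower by DESeq2 (camera down, adjusted p = 0.0315, and adjusted p = 0.727 with an estimated correlation). Without biopsy 4, called members appeared in 6 lists, mesenchymal transition with 3 lower and growth factors with 2 higher and 3 lower among them, and without biopsy 2, 1 growth factor was lower.

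Surface drug targets had 1 of 29 lower adjusted over the list alone, 6 higher and 11 lower at an unadjusted p under 0.05 and 1 higher and 2 lower by DESeq2 (camera adjusted p = 0.081). MHC class I had 0 of 20 adjusted over the list alone, 2 higher and 2 lower at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.228), and MHC class II had 0 of 14, 2 higher and 1 lower, and 0 by DESeq2 (camera adjusted p = 0.9). Hypoxia and glycolysis genes had 1 of 35 lower adjusted over the list alone, 3 higher and 5 lower at an unadjusted p under 0.05 and 2 lower by DESeq2 (camera adjusted p = 0.9). Chemokines and receptors had 1 of 12 lower adjusted over the list alone, 1 higher and 3 lower at an unadjusted p under 0.05 and 3 lower by DESeq2 (camera adjusted p = 0.467). Dissociation stress genes had 0 of 28 adjusted over the list alone, 4 higher and 2 lower at an unadjusted p under 0.05 and 0 by DESeq2, with a median of 0.01 and a mean of -0.04 while camera pointed up (adjusted p = 0.82). The stromal and immune background list had 0 of 11 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.228).

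To compare regulatory with killer T cells of the same tumours, Treg-like and CD8 T-like sums were compared within biopsies 3, 4, 6 and 8, from 22 and 30, 460 and 2995, 156 and 140, and 39 and 198 cells. CCR8, a chemokine receptor of Tregs in tumours, rose by 7.94 ± 0.43 on the log2 scale (adjusted p = 2.6e-06), at 166 ± 73.1 CPM against 0.970 in CD8 T-like cells. CTLA4 and ICOS rose by 2.47 ± 0.32 (0.0036) and 2.27 ± 0.21 (0.00015). The killer genes IFNG and GZMA, the residency integrin gene ITGA1 and the protease gene CTSW were lower, by -5.30 ± 0.56, -5.25 ± 0.58, -4.73 ± 0.40 and -4.46 ± 0.31, as was KLRC1 at -5.19 ± 0.45. All of these went the same way in 4 of 4 biopsies. TIGIT was higher in 4 of 4 but not called (1.33 ± 0.33, adjusted p = 0.076), and PDCD1 (-0.82 ± 0.42, 0.46), LAG3 (-1.26 ± 0.63, 0.5) and HAVCR2 (-0.68 ± 1.07, 0.92) were not called. The value of HAVCR2 turned to 0.66 with DESeq2 and to 0.72 without biopsy 4.

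Cytotoxic effectors were lower in 10 of 18 members and higher in 0 (11 and 0 adjusted over the list alone, with 0 higher at an unadjusted p under 0.05 and by DESeq2, camera adjusted p = 6.6e-36, and adjusted p = 0.0098 with an estimated correlation). Checkpoint genes were higher in 4 of 23 and lower in 2 (8 and 3 adjusted over the list alone, camera adjusted p = 0.0009, and adjusted p = 0.121 with an estimated correlation), with 1 lower without biopsy 6 and 4 without biopsy 8. The fourth, BTLA (1.89 ± 0.38), was not called without biopsy 3 (adjusted p = 0.0873) or biopsy 4 (0.292). Chemokine and receptor genes were higher in 1 of 15 and lower in 2 (2 and 4 adjusted over the list alone), with CCL5 (-5.25 ± 0.47) and CCL3 (-4.33 ± 0.44) lower, a median of 0.05 and a mean of 0.25 while camera pointed down (adjusted p = 0.637). Without biopsies 3 and 4, 2 and 3 members were higher. Proliferation genes were lower in 2 of 40 and higher in 0 (2 and 0 adjusted over the list alone, with 0 higher at an unadjusted p under 0.05 and by DESeq2, camera adjusted p = 0.00062, and adjusted p = 0.729 with an estimated correlation). The lower members were BUB1 (-1.74 ± 0.33, not called without biopsy 4, adjusted p = 0.243) and TYMS (-1.43 ± 0.29, not called without biopsy 3, 4 or 6, adjusted p = 0.124, 0.114 and 0.25). Their number was 1, 0, 0 and 17 without biopsies 3, 4, 6 and 8. Dissociation stress genes had 0 of 24 called (0 adjusted over the list alone, with 4 higher and 3 lower at an unadjusted p under 0.05 and 0 by DESeq2), with a median of -0.02 and a mean of 0.03 while camera pointed up (adjusted p = 0.637). Without biopsy 8, 1 stress member was higher and 2 lower. Of the epithelial background markers, most of them outside the tested genes, 0 of 10 differed by edgeR adjusted over the list alone, and 0 at an unadjusted p under 0.05.

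In all, 117 of 6843 genes were higher and 81 lower in Treg-like cells, 142 and 56 with library-size scaling. The total of 198 was 125 without biopsy 4, 40 without biopsy 6 and 306 without biopsy 8. Outside the lists, FANK1 (4.71 ± 0.41), FBLN7 (4.17 ± 0.49), EPHX2 (3.62 ± 0.38), SOCAR (3.29 ± 0.48) and LAPTM4B (3.16 ± 0.33) were the highest, with SOCAR not called without biopsy 6 (adjusted p = 0.101). F2R (-3.41 ± 0.44), MXRA7 (-2.92 ± 0.38), ATP10A (-2.87 ± 0.59), NUCB2 (-2.38 ± 0.28) and TRAT1 (-2.31 ± 0.33) were the lowest, with ATP10A not called without biopsy 3, 6 or 8 (0.127, 0.143 and 0.0639).

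To relate epithelial state to immune makeup, 3 relations were tested across the 6 biopsies with an epithelial-like sum. The luminal minus basal level was 4.33, 3.81, 3.79 and 6.42 log2 units in biopsies 2, 3, 6 and 8 but -7.62 and -5.37 in biopsies 1 and 4, which expressed the basal genes. MHC class II genes averaged 3.92 ± 0.92 log2(CPM + 1) (SD, n = 6) in the epithelial-like sums and proliferation genes 4.82 ± 0.41. The Pearson r of MHC class II level and T/NK-like share of non-epithelial cells was 0.08 (exact permutation p = 0.964, adjusted 0.964). Spearman rho was -0.09 (0.919, adjusted 0.919). Without the 2 biopsies farthest from the median share r was 0.88 over 4 biopsies (permutation p = 0.25), too few to decide. For the luminal minus basal level the biopsies fall into separate clusters of 4 and 2, each under 6, so no pooled value is given for its relations to the T/NK-like share and to proliferation.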

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

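Of the tests in this part, those that read free RNA gene by gene and low depth in biopsy 5 were chosen only after the result was seen. Each value below was marked because 1 biopsy lay far from the others, by a test that chance meets in about 5% of groups, and 8 of the 29 groups tested met it. In biopsy 6, myeloid-like cells made up 22.4% (next highest 6.49%), mast-like cells 5.33% (1.26%), plasma-like cells 13.2% (4.70%) and plasmacytoid dendritic-like cells 2.17% (0.523%). In biopsy 7, fibroblast-like cells made up 13.3% (next highest 5.67%) and mural-like cells 7.83% (1.48%). In biopsy 4, T/NK-like cells made up 62.1% (next highest 29.6%). The myeloid-like and fibroblast-like values depend on the naming rule set after the clusters were viewed. With mixed clusters named, biopsy 5 was 92% myeloid-like and biopsy 1 was 85.7% fibroblast-like, and at resolution 2 biopsy 5 was 64% myeloid-like. Shares of 1 biopsy sum to 100%, so these values are not independent of each other, and no biological explanation was tested, since the labels put all biopsies in 1 group. FGFR3 reached 297 CPM in the epithelial-like sum of biopsy 3, against a next highest value of 90.5 CPM. An alteration of the gene was not examined.

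The unnamed cells of biopsies 1 and 5, 88.3% and 88.9% of their cells, carried markers of several compartments at once. Low depth alone is argued against for biopsy 1, since named cells of other biopsies thinned to 900 UMIs held UMIs of 3 or more compartments in 16.6% of cells, against 98.8% of the unnamed cells of biopsy 1, although the highest single group among those named cells reached 61.4%. At most 6.57% of the cells of the compared biopsies were unnamed, too few for the choice of named cells to make this difference, and 1321 unnamed cells of biopsy 1 were too shallow to enter. For biopsy 5, at 69.2%, low depth stays open. Free RNA spread over all droplets stays open. A test on any marker per droplet gave an odds ratio of 0 but was saturated and decides nothing, and over 32 pairs of single genes in biopsy 1 the median odds ratio was 0.702 (quartiles 0.590 to 0.797), which cannot tell. In biopsy 5 the median over 16 pairs was 0.57 (0.447 to 0.631), with 0 pairs between the bounds set for independence, against 8 in biopsy 1, and the test on any marker gave 0.593 (0.334 to 1.05). No biological explanation was tested, and shares of named classes in these 2 biopsies rest on the few cells that could be named.

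Epithelial markers were found at a low level in T/NK-like sums, a median of 0.0998% of their UMIs. Over these markers the T/NK-like sum matched the epithelial-like sum of its own biopsy best in 6 of 6 biopsies, which is consistent with free RNA from the same biopsy. The 5% of the kept T/NK-like cells with the most epithelial UMIs held a median of 20.5% of them, so a few cells did not carry most of this RNA. Cells with the highest doublet scores and clusters of mixed markers had been set aside before, so doublets before that removal are not decided. A low true expression in lymphocytes was not tested.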

How the results depend on the processing

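The alternatives with the other classes as 1 group, with at least 1000 UMIs per cell and with clusters of mixed markers named were chosen only after the data were seen. Over the alternatives other than leaving out a biopsy, the counts of called genes stayed within 1.5 times the reported count in 84 cases, were higher in 9 and lower in 10. Named genes kept direction and side of the threshold in 2672 cases, lost a call in 178, gained one in 4 and reversed in 9. With a biopsy left out, the counts were similar in 46 cases, higher in 3 and lower in 9, and named genes were the same in 1514, weaker in 98, stronger in 2 and reversed in 4. The median share over the 8 biopsies moved by less than the spread between biopsies in all 65 cases, 13 classes (unnamed cells included) under 5 alternatives. Shares within a biopsy moved further in some cases, myeloid-like cells of biopsy 5 from 3.06% to 64% at resolution 2 and 92% with mixed clusters named, fibroblast-like cells of biopsy 1 from 5.67% to 85.7% with mixed clusters named, and epithelial-like cells of biopsy 2 from 87.7% to 54.6% at resolution 2.

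With the other classes as 1 group, the totals were 1786 for epithelial-like, 766 for fibroblast-like, 286 for endothelial-like, 1208 for myeloid-like, 1101 for T/NK-like, 47 for B-like and 599 for plasma-like cells. By the construction of that alternative the differences between the other classes add to the error. In it CD274 (-0.52) and FAP (-1.67) in epithelial-like and CD86 (-0.22) in B-like cells reversed. Library-size scaling gave 8701 calls for plasma-like cells and shifted the median of all genes by -1.64 there, by 0.24 for epithelial-like, 0.22 for fibroblast-like, 0.39 for endothelial-like, 0.27 for myeloid-like, 0.45 for T/NK-like and 0.11 for Treg-like cells and by -0.13 at the luminal end. RLE and DESeq2 shifted the B-like comparison by -0.14 and -0.16. The reference of 1 group shifted fibroblast-like, endothelial-like, myeloid-like, T/NK-like and plasma-like cells by -0.12, -0.13, -0.16, -0.19 and -0.19.

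The luminal comparison, with 20 calls, gave 35 with library-size scaling, 385 with DESeq2, 271 without a filter and 182 in thinned sums. It gave 34 with thinning to 1000 UMIs and 0 to 217 with a biopsy left out. edgeR called 0 without the patient block or with a split at the median of the score (187 and 3230 at an unadjusted p under 0.05). The Treg-like comparison, with 198 calls, gave 511 without a filter, 69 without the patient block, 372 with at least 50 cells per sum (2 biopsies), 310 at resolution 2, and 40 to 306 with a biopsy left out. With a biopsy left out the class totals ranged from 2360 to 3682 for epithelial-like, 1937 to 2710 for fibroblast-like, 1060 to 2050 for endothelial-like, 1821 to 2723 for myeloid-like, 1499 to 2280 for T/NK-like, 995 to 1952 for B-like and 960 to 2121 for plasma-like cells. Fewer samples are part of that construction, and for the rest of these changes the cause was not tested.

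FAP in epithelial-like cells reversed with DESeq2 (-0.30), at resolution 2 (-0.01), with mixed clusters named (-0.23) and with a biopsy left out (-1.52 to 0.96, with -0.07 without biopsy 1). At the luminal end CD276 reversed with library-size scaling (-0.02), in thinned sums (-0.34) and without biopsy 6 (-0.01, range with a biopsy left out -0.01 to 0.23), and in Treg-like cells HAVCR2 reversed with DESeq2 (0.66) and without biopsy 4 (0.72, range -1.36 to 0.72). None of FAP, CD276 and HAVCR2 was called under the reported settings, and FAP was called with at most 10% mitochondrial UMIs (1.39). The r of MHC class II level and T/NK-like share, 0.08, turned to -0.01 with log2(CPM + 10) and to -0.08 at resolution 2. The rho turned from -0.09 to 0.26 with at most 10% mitochondrial UMIs. The 2 relations given no pooled value were 0.67 and 0.36 over 4 biopsies (permutation p = 0.333 and 0.833). The endothelial-like comparison gave no value with at least 50 cells per sum or at most 10% mitochondrial UMIs, which left too few sums. The simulated class comparison was run for epithelial-like cells only, so the effect of depth on the other classes was not measured.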

Other observations

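Of the tests in this part, the B-like and plasma-like comparisons, the random score lists and the use of thinned sums as a test of depth were chosen only after the data were seen. B-like cells expressed MHC class II genes and CXCR5, a homing receptor gene of B cells, and plasma-like cells the receptor gene CCR10. In B-like sums of 3 biopsies (136 to 1853 cells), 14 of 15 MHC class II members were higher and 0 lower (14 and 1 adjusted over the list alone, with 1 lower at an unadjusted p under 0.05 and 0 by DESeq2, camera adjusted p = 2.0e-20, and adjusted p = 0.0023 with an estimated correlation). HLA-DOA, HLA-DRA, HLA-DMB and HLA-DQB1 rose by 4.50, 4.31, 4.29 and 4.09, each in 3 of 3 biopsies. CXCR5 averaged 97.0 ± 14.0 CPM (SD, n = 3) against at most 4.42 in another class, and CCR7 rose by 5.13 ± 0.77, although myeloid-like sums held 75.2 CPM of it against 143 in B-like sums, and its call ended with the other classes as 1 group (adjusted p = 0.344). CXCL2 and CX3CR1 had 0 UMIs. A floor of 3 UMIs over the class lay about 37.6-fold and 24.8-fold below the arithmetic mean CPM of the other classes. For CX3CR1 that mean came from T/NK-like (37.3 CPM) and myeloid-like sums (38.6), with at most 0.667 in any other class. The call of CXCL2 was lost without biopsy 4, 7 or 8 (adjusted p = 0.111, 0.267 and 0.0824). That of CX3CR1 was lost without biopsy 6, 7 or 8 (1, 0.21 and 0.153).

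Chemokines and receptors were higher in 5 of 42 and lower in 2 (6 and 2 adjusted over the list alone, camera up, adjusted p = 0.532, median -0.96, mean -0.53), with 1, 1, 0 and 0 lower without biopsies 4, 6, 7 and 8. Checkpoint genes were higher in 8 of 37 and lower in 4 (10 and 5 adjusted over the list alone, camera up, adjusted p = 0.479, median -0.64, mean 0.08), with 2, 1 and 1 lower without biopsies 4, 7 and 8. BTLA rose by 4.57 ± 0.53, CD86 by 3.77 ± 0.71 (78.3 CPM against 365 in myeloid-like sums, and -0.22 with the other classes as 1 group) and NECTIN2 differed by -4.53 ± 0.49, while SIGLEC10 averaged 38.9 ± 6.90 CPM against 50.6 in myeloid-like sums. Proliferation genes were higher in 1 of 43, MCM5 (1.75 ± 0.46), and lower in 0 (1 and 0 adjusted over the list alone, with 0 lower at an unadjusted p under 0.05 and by DESeq2, camera adjusted p = 0.655). MCM5 was not called without biopsy 7 (1.34, adjusted p = 0.159), where 1 member was lower, and 2 members were higher without biopsy 8. Of the 18 epithelial background markers, most of them outside the tested genes, 3 were lower adjusted over the list alone and 4 at an unadjusted p under 0.05. In all 909 genes were higher and 1000 lower, 724 and 1326 by DESeq2, with a total of 995 without biopsy 7 and 1201 without biopsy 8. With the other classes as 1 group 38 were higher and 9 lower, and the calls of all the MHC class II members ended. Outside the lists CD37 (5.15), RASGRP2 (4.48), SIT1 (4.45), FGD2 (4.43) and HVCN1 (4.35) were the highest and OAF (-5.95), SMAD1 (-5.63), TMEM51 (-5.57), MTUS1 (-5.31) and KIFC3 (-5.14) the lowest. With the other classes as 1 group only CXCR5 and HVCN1 of the genes named for B-like cells were called.

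In plasma-like sums of 3 biopsies (140 to 329 cells), CCR10 rose by 7.27 ± 0.57 and CD27 by 5.58 ± 0.65. MHC class II members were lower in 4 of 15 and higher in 0 (4 and 0 adjusted over the list alone, with 1 higher at an unadjusted p under 0.05 and 0 by DESeq2, camera adjusted p = 0.128), and 1, 0 and 2 were lower without biopsies 4, 6 and 7. They were HLA-DPB1 (-2.76), CIITA (-2.73), HLA-DRA (-2.56) and HLA-DMB (-2.30), none called without biopsy 6 (adjusted p = 0.163, 0.119, 0.237 and 0.33). Checkpoint genes were higher in 5 of 37 and lower in 4 (5 and 4 adjusted over the list alone, camera adjusted p = 0.729), with 3, 1 and 3 higher and 1 lower each without biopsies 4, 6 and 7. PVR (-3.25), TNFRSF18 (2.65) and ADORA2A (2.52) were not called without biopsy 6 (0.098, 0.0807 and 0.129). T/NK-like sums held 289 CPM of TNFRSF18, against 50.7 in plasma-like sums. Chemokines and receptors were higher in 2 of 42 and lower in 1 (2 and 0 adjusted over the list alone, with 3 lower at an unadjusted p under 0.05 and 1 by DESeq2, camera adjusted p = 0.581). CCR2 averaged 20.6 ± 27.6 CPM, against 24.6 in myeloid-like sums, and was not called without biopsy 4 (0.0795). CCL2 (-2.83) was not called without biopsy 4, 6 or 7 (0.142, 0.181 and 0.0713).

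Proliferation genes in plasma-like cells were higher in 1 of 43 and lower in 2 (0 and 0 adjusted over the list alone, with 1 higher and 12 lower at an unadjusted p under 0.05 and 1 and 9 by DESeq2, camera down, adjusted p = 0.0038, and adjusted p = 0.83 with an estimated correlation). CENPF (-2.84), CDC6 (2.11) and MCM3 (-1.35) were not called without biopsy 6 (0.278, 0.224 and 0.331), and 4 members were lower without biopsy 8. Epithelial-like sums held 23.4 CPM of CDC6, against 19.4 in plasma-like sums. Of the 18 epithelial background markers, most of them outside the tested genes, 0 differed by edgeR adjusted over the list alone, with 2 higher at an unadjusted p under 0.05. In all 1298 genes were higher and 759 lower, 235 and 8466 with library-size scaling, 493 and 106 with the other classes as 1 group, and the total of 2057 was 1382 without biopsy 4 and 960 without biopsy 6. Outside the lists SPAG4 (6.12), ZBP1 (5.69) and SLAMF7 (5.55) were the highest, with CHPF at 206 ± 41.5 and BHLHE41 at 132 ± 32.9 CPM, and PLXND1 (-4.31), SPRY1 (-4.18), GASK1B (-4.04), SVIL (-3.79) and TTYH3 (-3.70) the lowest. SPRY1 was not called without biopsy 6 (0.148) and GASK1B not without biopsy 4 (0.0703). With the other classes as 1 group only CCR10, SPAG4, ZBP1, SLAMF7 and TTYH3 of the genes named for plasma-like cells were called.

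To count calls under other groupings, class names were dealt out at random within biopsies. In each of the 7 class comparisons 1 of 22 deals, the real one, reached the real count. The real counts and the highest of the others were 3278 and 17 for epithelial-like, 2522 and 144 for fibroblast-like, 1988 and 44 for endothelial-like, 2697 and 1 for myeloid-like, 2237 and 41 for T/NK-like, 1909 and 5 for B-like and 2057 and 199 for plasma-like cells. These deals decide nothing about chance, because the classes were made by clustering the same cells on expression, which alone makes random names give fewer calls. The number of deals was lowered to limit running time after a longer series had been seen, in which the highest others were larger for several classes but below the real counts.

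For Treg-like cells 1 of 32 splits, the real one, reached the real count of 198, but only 8 of these splits part all 4 pairs of sums from the same biopsy, too few for a share under 0.05. The highest of the other 7 called 0 by edgeR, and the counts of these splits at an unadjusted p and by other tools were not computed. For the luminal comparison 3 of 100 drawn splits, the real one included, reached the real count of 20. Only 14 of the drawn splits part all 5 pairs, too few for a share under 0.05, and the highest of the other 13 called 2. The 2 other splits that reached the real count called 417 each. They are mirror images, and are the real contrast over biopsies 3, 6 and 8 with the pairs of biopsies 2 and 4 kept together. Scores from random lists reached 20 calls in 15 of 20 lists, so any split of these cells along a score may give this number. Sums of thinned counts gave 182 calls, within the 0 to 217 of leaving out a biopsy, so depth of the ends stays open.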
